A study of Homo sapiens with 10 samples.

How the data were processed

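CUT&Tag was performed in HCT116 cells, an established human colorectal carcinoma line. In CUT&Tag an antibody tethers a fused transposase (pAG-Tn5) to chromatin, and the enzyme cuts and tags DNA near the bound protein. Antibodies were against POLR1A, the largest subunit of RNA polymerase I, POLR2A, the largest subunit of RNA polymerase II, the promoter mark H3K4me3 and the heterochromatin mark H3K9me3. Per the labels, 100000 to 200000 cells entered each replicate, the Active Motif CUT&Tag-IT kit was used, and 3 replicates were made on separate days from freshly thawed aliquots. The 10 samples used here were 3 for POLR1A, 3 for POLR2A, 3 for H3K9me3 and 1 for H3K4me3. Control antibody samples were not used here.

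The deposited data used were 4 peak lists in the format of MACS2, 1 for each target. The H3K4me3 list belongs to its 1 sample, and the other lists name no replicate. The fold enrichment of each peak is a linear ratio computed by the authors, and it was used only to rank and describe peaks within its own list. The lists also carry −log10 p and −log10 q values as the authors deposited them, and the position of the summit as an offset from the peak start. The lowest −log10 q in each list lay just above 1, which corresponds to a q threshold of 0.1. The caller's settings, its control and whether replicates were pooled are not given in the sources used here. The submitters' processing notes name FastQC 0.12.0, STAR, SAMtools 1.6, deepTools 3.1.1, RSEM 1.3.3, HTSeq 2.0.2 and DESeq2 1.44.0, without roles, and the builds GRCh38 and hg38. Read depth per sample is unknown from peak lists, so differences in list length between targets could come from depth, antibody or biology. There were no values per replicate and no mean, SD or p across replicates could be given. Treatment of reads from repeated sequence is likewise not given in the sources used here, and it decides whether peaks can appear on multi-copy genes.

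Peaks on chromosomes 1 to 22 and X were analysed, after merging touching peaks, which changed no list. Peaks on chromosome Y, the mitochondrial genome and other contigs were counted only. Genes came from a RefSeq table of the same assembly with 59792 genes. It holds gene starts and ends without strand or exons, and 679 genes whose positions belong to scaffolds or patches were left out. The test fixed at the outset used windows around the 5′ end, which needs strand. Windows of 1 kb on each side of both gene ends were used in its place, called gene ends below, for 19821 protein-coding genes with 39642 ends. Promoter and terminator could not be separated in this way, nor exon and intron.

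A pair of peaks overlapped if they shared a base. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Chance overlap came from 1000 random placements of the first list on the same chromosomes, with one-sided and two-sided p. The smallest values these can give are 0.001 and 0.002. Assembly gaps could not be excluded from the placements, which by itself lowers chance slightly. The placements also ignore gene density and open chromatin. Their p says only whether lists overlap more or less than peaks of the same size placed at random. Differences in share used chromosomes as units, with 100000 sign permutations, two-sided, and intervals from 2000 resamplings of chromosomes. Chromosomes entered with at least 10 peaks in both groups. The smallest permutation p is 1e-05. Common odds ratios were Mantel-Haenszel estimates with resampled chromosomes. Median log2 fold enrichment was compared by 100000 permutations of peak labels, two-sided.

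Gene lists and the rule for named genes were fixed before the data were examined, as were the tests, except for 3 chosen after seeing the data: the H3K4me3 overlap of POLR2A peaks with and without POLR1A, the odds ratio of both polymerases among H3K4me3 peaks, and the odds ratio of POLR1A with H3K9me3 at gene ends. The groups of equal size by fold enrichment were likewise not fixed beforehand. They are given without a test, except in the comparison for the transposase background among the flagged results. Of 31 lists, 26 of protein-coding genes were tested by Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over 155 tests of lists and targets. Lists of non-coding genes are given as shares. The olfactory receptor list, which holds many pseudogenes, was first given as a share only and was tested over its protein-coding members after the first values had been seen. The transfer RNA list was added after the data were examined. Neighbouring members of a family can share 1 peak, so list p-values assume more independence than there is. Named genes were the 15 with the highest POLR1A fold enrichment at ends with both polymerases, the 8 highest at ends without POLR2A, the 8 whose bodies hold the strongest POLR1A peaks on H3K9me3, up to 4 per list by POLR1A fold enrichment or 2 by another target, and the 8 highest for POLR2A, H3K4me3 and H3K9me3. Genes that share a peak are named together.

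Alternatives were a −log10 q of at least 5, an overlap of at least 50% of the first peak, 250 bp on each side of the summit, merging within 500 bp, lists cut to equal length by −log10 q, leaving out chromosomes 9, 13, 14, 15, 19, 21 and 22, rotation of whole lists as the chance model, matching on peak width, windows of 500 bp and 2 kb, and distance limits of 500 bp and 5 kb. Leaving out peaks within 500 kb of chromosome ends or 1 Mb of the longest gene-free interval of each chromosome, and leaving out sites present in all 4 lists, were chosen after seeing the data. The overlap count, the random placements, the chromosome test, the odds ratios, the median permutation and the gene list tests were tested on simulated data. In simulations with 3812 peaks, a planted overlap of 5% was recovered as 4.92% and one of 50% as 50.1%. Equal shares were called different in 2.5% of simulations. In 40 simulated families of gene list tests with equal shares of 10%, 5% gave a call, and a share of 35% planted in the 5 longest lists was called in 99.8% of cases. Genes were drawn independently there, and no share was planted in the shorter lists, so how often those would be called was not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.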

Results

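The data described where both large polymerase subunits and a pair of opposed histone marks were found in HCT116 cells. On chromosomes 1 to 22 and X the POLR1A list held 3812 peaks with a median width of 290 bp, covering 1.28 Mb. The POLR2A list held 19997 peaks with a median width of 244 bp, covering 5.95 Mb. The H3K4me3 list held 17181 peaks with a median width of 802 bp, and the H3K9me3 list 16414 peaks with a median width of 496 bp. A −log10 q of at least 5 was reached by 37.99% of POLR1A peaks, 48.0% of POLR2A peaks, 90.1% of H3K4me3 peaks and 24.2% of H3K9me3 peaks. Each target had 1 list, that of H3K4me3 from 1 sample, so no value below has a replicate error. Intervals cover counting error or the spread between chromosomes.

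The first comparison asked how far the sites of RNA polymerase I, which transcribes ribosomal RNA genes, coincide with those of RNA polymerase II, which transcribes protein-coding genes. Of the 3812 POLR1A peaks, 2733 overlapped a POLR2A peak (71.7%, 95% interval 70.2 to 73.1), against 0.543% in random placements (132 times, one-sided permutation p = 0.001 over 1000 placements, the smallest these can give). Seen from the longer list, 2747 of the 19997 POLR2A peaks overlapped POLR1A (13.7%). With lists of equal length the shares were 45.5% of POLR1A peaks and 45.4% of POLR2A peaks. Summits lay close together. The median POLR1A summit was 113 bp from the nearest POLR2A summit, and 73.8% lay within 1 kb against 1.64% by chance (one-sided permutation p = 0.001). A further 20.0% lay more than 10 kb away.

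BRD3OS on chromosome 9 (gene 134025481 to 134031587) held the strongest shared site at a gene end, with a POLR1A fold enrichment of 22.4, the highest POLR2A value at any protein-coding gene end (34.5) and an H3K4me3 value of 13.2. The POLR1A peak spanned 134025027 to 134025413 and ended just outside the gene. The POLR2A peak spanned 134025021 to 134025415 and the H3K4me3 peak 134025042 to 134025493. GUK1, the guanylate kinase gene on chromosome 1, followed with a POLR1A fold enrichment of 14.1 and a POLR2A value of 20.0. SRGAP2 on chromosome 1, one of a set of near-identical copies and therefore uncertain, had a POLR1A value of 13.9, and FAM86B2 on chromosome 8, also of a multi-copy family, had 13.1. The rest of the 15 genes ranged from 12.5 at SENP2, which encodes a SUMO protease, to 13.3 at GNG8, a G protein gamma subunit gene, and included HDGFL2 (13.3), CCDC110 (13.03), AGFG2 (12.7), TRIM37 (12.6) and TMEM216 (12.6). The neighbours ODAD3 and PRKCSH shared a POLR1A peak of 12.99, and LEPR and LEPROT shared one of 12.8. H3K9me3 was found at the ends of 3 of the 15 genes. The peak beside TMEM216, a ciliary gene, had an H3K9me3 fold enrichment of 26.8, with POLR2A at 7.46. FAM86B2 and SRGAP2 had H3K9me3 at 6.46 and 4.91. Beside TMEM216 the POLR1A, POLR2A and H3K9me3 peaks all began at 61391246, and at GNG8 the POLR1A and POLR2A peaks both began at 46634246. Whether such shared edges come from mapping was not tested, so these sites are uncertain as well. Among the genes with the highest POLR2A values, PARK7 (POLR2A 31.1), NUP98 and PGAP2 (shared, 28) each had a POLR1A value of 11.9 and OGA (POLR2A 26.0) had 7.59, while JPT1 (POLR2A 28.1) and INTS6 (POLR2A 25.9) held no POLR1A peak at their ends.

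Of 19821 protein-coding genes, 2213 had a POLR1A peak at a gene end (11.2%), 8192 a POLR2A peak (41.3%), 10832 an H3K4me3 peak (54.7%) and 535 an H3K9me3 peak (2.70%). POLR1A and POLR2A met at the same end of 2114 genes, which is 95.5% of the genes with POLR1A and 25.8% of those with POLR2A. Only 87 genes had POLR1A and no POLR2A at either end. The odds of a POLR1A peak at ends with POLR2A were 17.5 times those at ends without it, within classes of H3K4me3 (resampled interval 12.9 to 24.5). Among ends with H3K4me3, POLR1A was present at 26.5% of those with POLR2A and 2.03% of those without. At a −log10 q of at least 5 the count of genes with both fell to 1052 and the odds ratio was 90.2. At ends with POLR1A and no POLR2A, the highest POLR1A values were at ERV3-1 and its readthrough gene ERV3-1-ZNF117 (6.85), ATP5MC3, a subunit gene of the mitochondrial ATP synthase (6.80), EFHD1 (6.63), ZDHHC11 (6.16), MARVELD3 (5.91), the splicing factor gene PRPF18 (5.90) and C4orf36 (5.88). ZDHHC11 alone among them lacked H3K4me3 at its ends, and it carried H3K9me3 at 4.57.

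POLR1A presence rose with the strength of the POLR2A peak. With POLR2A peaks in 10 groups of equal size by fold enrichment, 0.75% overlapped POLR1A in group 1, the weakest, 30.2% in group 9 and in group 10 57.0% (95% interval 54.8 to 59.2). The corresponding rise along the H3K4me3 list was from 5.99% to 19.03%, level from group 7 onward (19.1%). Within the POLR1A list, 20.9% of the weakest group and 92.9% of the strongest overlapped POLR2A. The median POLR1A fold enrichment was 6.04 with POLR2A and 4.31 without (log2 difference 0.49, permutation p = 1e-05, the smallest possible). Single peaks of 1 list were the units of this permutation and need not be independent, so its p covers the spread between peaks only.

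**Figure D1:**
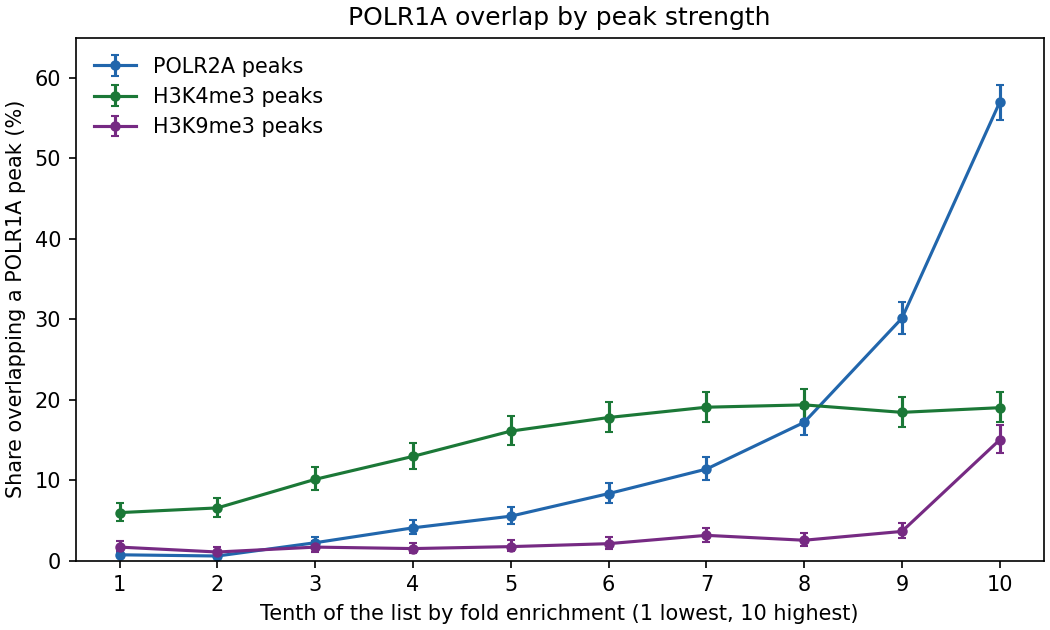
Share of peaks overlapping a POLR1A peak (y axis, %) in 10 groups of equal size of the POLR2A, H3K4me3 and H3K9me3 lists by fold enrichment (x axis, 10 highest), with exact 95% binomial intervals. The POLR2A line climbs to 57.0% in group 10, where H3K4me3 peaks are at 19.03% and H3K9me3 peaks at 15.04%.

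The second comparison set both polymerases against H3K4me3. Of POLR1A peaks 65.8% overlapped H3K4me3 (71.1 times chance), and of POLR2A peaks 50.04% (61.1 times chance, both one-sided permutation p = 0.001). The difference was 15.8 percentage points (interval 12.9 to 18.3, permutation p = 1e-05, higher in 22 of 23 chromosomes). It depended on which peaks were counted. At a −log10 q of at least 5 it was 2.67 points (interval -3.78 to 7.84, permutation p = 0.649), and with lists of equal length it turned to -13.8 points (27.9% for POLR1A and 41.7% for POLR2A). Matched on peak width it was 7.56 points. Inside the POLR2A list, in a comparison chosen after seeing the data, peaks with POLR1A overlapped H3K4me3 in 85.9% of cases and those without in 44.3% (permutation p = 1e-05, higher in 23 of 23 chromosomes). With equal list lengths this difference was 7.88 points.

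By summit position, 45.5% of POLR1A peaks, 37.1% of POLR2A peaks, 60.05% of H3K4me3 peaks and 2.41% of H3K9me3 peaks lay at protein-coding gene ends, where random POLR1A placements put 3.05%. The order of the polymerases turned with the peaks counted: at a −log10 q of at least 5 the shares were 55.4% for POLR1A and 57.8% for POLR2A, and with equal list lengths 45.5% and 70.9%. Intergenic shares were 22.2%, 18.6%, 9.06% and 53.2% in the same order. The largest class of POLR1A peaks carried POLR2A and H3K4me3 without H3K9me3, with 2097 peaks (55.01%). Another 696 (18.3%) overlapped none of the other lists and had the lowest median fold enrichment, 4.03. The genes with the highest H3K4me3 values mostly had little POLR2A and no POLR1A at their ends. Among them NDUFA3, of respiratory complex I, had an H3K4me3 value of 33.6 with POLR2A of 2.80, and AK6 and TAF9, which share an end, had 31.9 with POLR2A of 4.67. B2M, encoding the light chain of MHC class I, and its neighbour PATL2 shared an H3K4me3 value of 32.3 with no POLR2A peak, as did BOLA2B and SLX1A at 32.2, which lie in duplicated sequence.

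**Figure D2:**
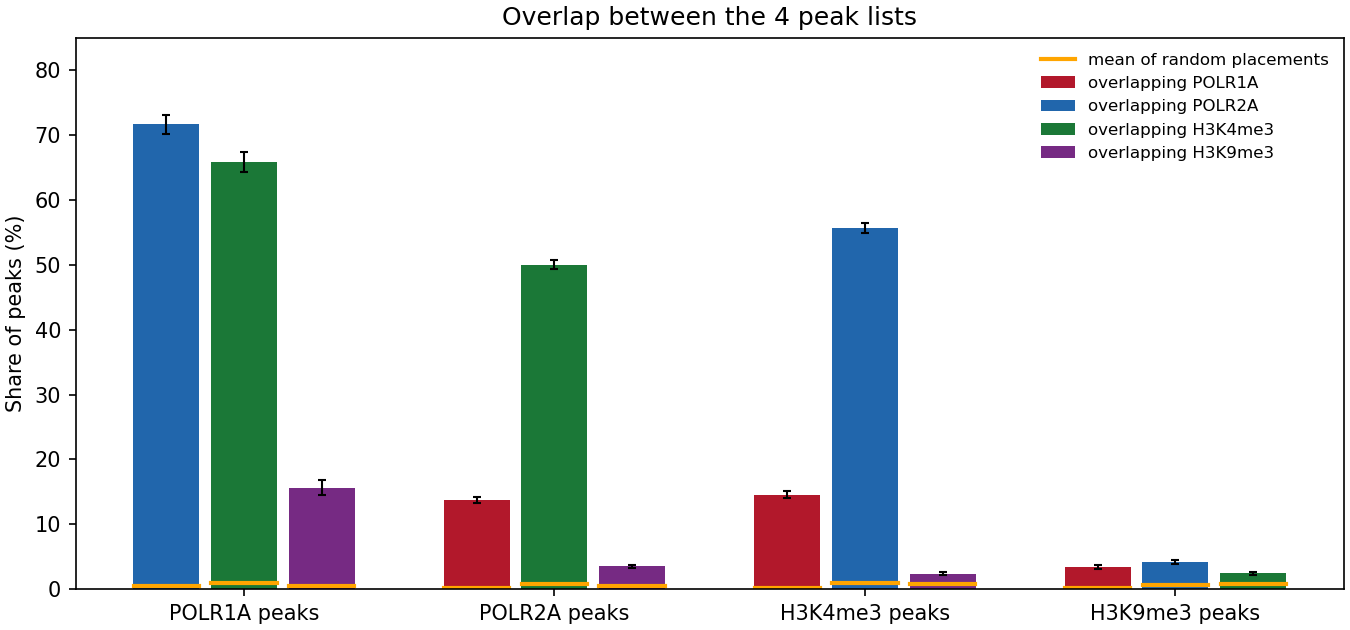
Share of the peaks of each list (x axis) overlapping each other list (y axis, %), with exact 95% binomial intervals and, as orange lines, the mean of 1000 random placements. POLR1A peaks overlap POLR2A in 71.7%, H3K4me3 in 65.8% and H3K9me3 in 15.6% of cases.

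The third comparison concerned H3K9me3. POLR1A peaks overlapped H3K9me3 in 15.6% of cases (595 peaks, 29.4 times chance) and POLR2A peaks in 3.53% (7.18 times chance, both one-sided permutation p = 0.001). Over 9 alternatives the shares ranged from 9.48% to 18.5% for POLR1A and from 1.83% to 3.565% for POLR2A. In the main analysis the difference was 12.1 points (interval 9.68 to 14.8, permutation p = 1e-05) and was positive in 23 of 23 chromosomes. With peaks near chromosome ends and gene-free intervals left out and lists of equal length, it was 4.73 points (interval 3.47 to 6.52), and with equal length alone 7.63 points. Of the 595 POLR1A peaks on H3K9me3, 247 also carried POLR2A and H3K4me3, and these had the highest median fold enrichment of any class, 7.85. A further 218 had neither, of which 149 were intergenic and 100 lay in the margins of chromosome ends or gene-free intervals. H3K4me3 and H3K9me3 overlapped in 2.36% of H3K4me3 peaks and 2.47% of H3K9me3 peaks, 2.93 and 2.98 times chance.

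Within gene bodies the strongest POLR1A peaks on H3K9me3 were in GPR35, a G protein-coupled receptor gene on chromosome 2 (peak 240613499 to 240614018, POLR1A 28.5), the uncharacterised LOC124907874 on chromosome 2 (27.0), COL23A1, a collagen gene on chromosome 5 (21.3, with H3K9me3 of 21.6), SLC38A8 (15.99), TMEM242 (14.4), SERINC2 (14.04) and FAM72A with SRGAP2 (13.9). The sequence under these peaks was not examined for repeats. All of them lay outside the margins of chromosome ends and gene-free intervals, so leaving out the margins does not remove them. The highest H3K9me3 values in gene bodies were in ACSL3, an acyl-CoA synthetase gene (28.04), and TCF20 (27.6), followed by EML1 (22.2), COL23A1, MARCHF10 (19.1), RANBP2 with SH3RF3 (18.9) and DPP10 (18.9). The annotated span of RANBP2 (108719482 to 109842301) encloses that of SH3RF3 (109129205 to 109504634), so their shared value need not belong to RANBP2. At gene ends, the odds of POLR1A were 7.23 times as high with H3K9me3 as without (interval 5.22 to 10.1), within classes of presence of H3K4me3 and POLR2A, and 5.51 times (4.23 to 7.02) within classes of their fold enrichment. Both odds ratios were chosen after seeing the data.

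Heat shock and protein folding genes had POLR1A most often of the lists. POLR1A was at the ends of 12 of 18 (66.7%, against 11.1% of other genes, adjusted p = 3.2e-07), among them PDIA4 (9.83), the chaperone gene CALR (8.73), and HSPD1 and HSPE1, which encode the mitochondrial chaperonins and share a peak (8.14). Spliceosome and RNA-binding protein genes followed with 14 of 32, including HNRNPC (9.37), SNRPA (9.17), HNRNPD (8.5) and DDX5 (8.16), with an adjusted p of 2e-05. Translation factors had 12 of 34 (EIF4B 9.99, EEF1G 8.5, EIF2S1 7.29; adjusted p = 0.00094). Replication-dependent histone genes had 17 of 69, with H2BC11 and H2AC11 sharing a peak of 11.9 and H3C1 and H4C1 one of 8.24 (adjusted p = 0.006). Cytosolic ribosomal protein genes had 18 of 79, with RPS27A at 8.84, RPL7 at 7.81 and RPL41 at 6.72 (adjusted p = 0.012). All p-values for lists are from Fisher's exact test with Benjamini-Hochberg adjustment over 155 tests. At a −log10 q of at least 5 the translation factor, histone and ribosomal protein lists no longer passed, with shares of 8.82%, 5.80% and 7.59% against 5.36%, 5.36% and 5.35% of other genes.

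POLR1A was at the ends of 0 of 389 olfactory receptor genes, 0 of 54 cancer testis antigen genes, 0 of 53 clustered protocadherins and 0 of 39 HOX genes, each lower than in other genes. The HOX call was the least stable: it ended without the olfactory receptors among the tests (adjusted p = 0.05001, just above the threshold), with a window of 500 bp (adjusted p = 0.0736) and with equal list lengths (adjusted p = 0.0632). Equal lengths leave the POLR1A list uncut, so there the HOX share did not change and only the adjustment over the other tests did. At a −log10 q of at least 5 the cancer testis, protocadherin and HOX calls ended (adjusted p = 0.269, 0.269 and 0.509), with shares still at 0% and 5.38%, 5.38% and 5.37% in other genes. POLR2A was also called lower in olfactory receptor genes (4 of 389), cancer testis genes (1 of 54) and protocadherins (0 of 53), but not in HOX genes (10 of 39, adjusted p = 0.108). These lists hold too few genes with POLR2A for a lower share of POLR1A among them to be called. Among genes with POLR2A, POLR1A was more frequent in heat shock genes (12 of 14, against 25.7%, adjusted p = 2.9e-05), spliceosome genes (14 of 27, adjusted p = 0.012) and histone genes (17 of 39, adjusted p = 0.042). POLR2A was taken as present or absent here. POLR1A presence also rose with POLR2A strength, so these calls do not show a difference beyond that strength. The spliceosome call ended at a −log10 q of at least 5, where its share was 33.3% against 15.97% (51.9% against 25.7% in the main analysis), and with equal list lengths (57.1% against 46.5%). The histone call ended in the same settings with shares below the background (13.8% against 16.05% and 42.1% against 46.6%), and with a window of 500 bp (41.03% against 25.4%, adjusted p = 0.0927). Of cytosolic ribosomal protein genes with POLR2A, 18 of 71 had POLR1A (25.4%, against 25.8% of other genes with POLR2A), which was not called.

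The list of RNA polymerase I subunits and ribosomal DNA transcription factors had POLR1A in 5 of 16 cases, among them TBP (7.37), TAF1D (4.96), POLR1A and POLR1C (4.78 each). It did not pass adjustment (adjusted p = 0.0637) but did with a window of 500 bp (adjusted p = 0.0476). TBP, with the highest value, lies within the margins of chromosome ends and gene-free intervals. Other lists that did not pass were RNA polymerase III genes (6 of 22; MAF1 6.92, GTF3C2 5.03), RNA polymerase II genes (1 of 22, CCNT1 at 6.09), mitochondrial ribosomal proteins (15 of 77; MRPL4 7.65, MRPS7 7.19), ribosome biogenesis genes (9 of 40; UTP18 11.3, NPM1 10.4), oxidative phosphorylation genes (7 of 30; ATP5MC1 11.2, ATP5F1B 7.38), cell cycle genes (7 of 32; CDK4 10.6, CCNB1 8.38), p53 target genes (5 of 20; RRM2B 12.1, TP53I3 10.1), immediate early genes (2 of 26; JUN 5.31, SRF 4.69) and glycolysis genes (0 of 18, with POLR2A at 13 of them, PGK1 at 15.9). Of these, RNA polymerase III genes passed with a window of 2 kb (adjusted p = 0.0348) and cell cycle genes at a −log10 q of at least 5 (adjusted p = 0.0235). Among markers of cell types, POLR1A was at 0 of 27 intestinal epithelium genes, of which SOX9 had POLR2A at 16.2 and EPCAM at 12.5, 1 of 16 fibroblast genes (ACTA2, 3.61), 0 of 17 leukocyte genes, 0 of 19 neuronal genes and 0 of 18 liver genes.

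H3K9me3 was more frequent in zinc finger genes than in other genes. Of those on chromosome 19, 53 of 246 had H3K9me3 at an end (21.5% against 2.46%, adjusted p = 7.3e-31) and 103 had it in the body (41.9% against 13.2%, adjusted p = 1.7e-26). Of zinc finger genes on other chromosomes, 21 of 263 had it at an end (adjusted p = 6.3e-05) and 89 in the body (adjusted p = 8.3e-16), and the call at the ends did not hold without the margins (4.56%, adjusted p = 0.104). POLR1A was at 26 of the 246 genes (10.6%) and 30 of the 263 (11.4%), against 11.2% of other genes, and neither list was called, with ZNF584 at 9.89, ZNF333 and ZNF784 at 8.27, ZNF687 at 12 and ZNF143 at 9.60. H3K9me3 at the ends was also more frequent in spliceosome genes (5 of 32, 15.6% against 2.68%, adjusted p = 0.006) and histone genes (6 of 69, adjusted p = 0.03). The spliceosome call ended at a −log10 q of at least 5 (3.13% against 0.586%) and with equal list lengths (3.13% against 0.546%). The histone share fell to 0% in both settings, and its call also ended with a window of 2 kb (adjusted p = 0.114). In bodies, H3K9me3 was more frequent in protocadherins (19 of 53) and less frequent in olfactory receptors (12 of 389), cytosolic ribosomal proteins (2 of 79), mitochondrial ribosomal proteins (2 of 77), ribosome biogenesis genes (0 of 40) and HOX genes (0 of 39). Of these calls in bodies, only that of olfactory receptors held at a −log10 q of at least 5 and with equal list lengths, where far fewer genes had H3K9me3. The shares of the other lists stayed on the same side of other genes, such as 9.43% against 4.75% for protocadherins at a −log10 q of at least 5.

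**Figure D3:**
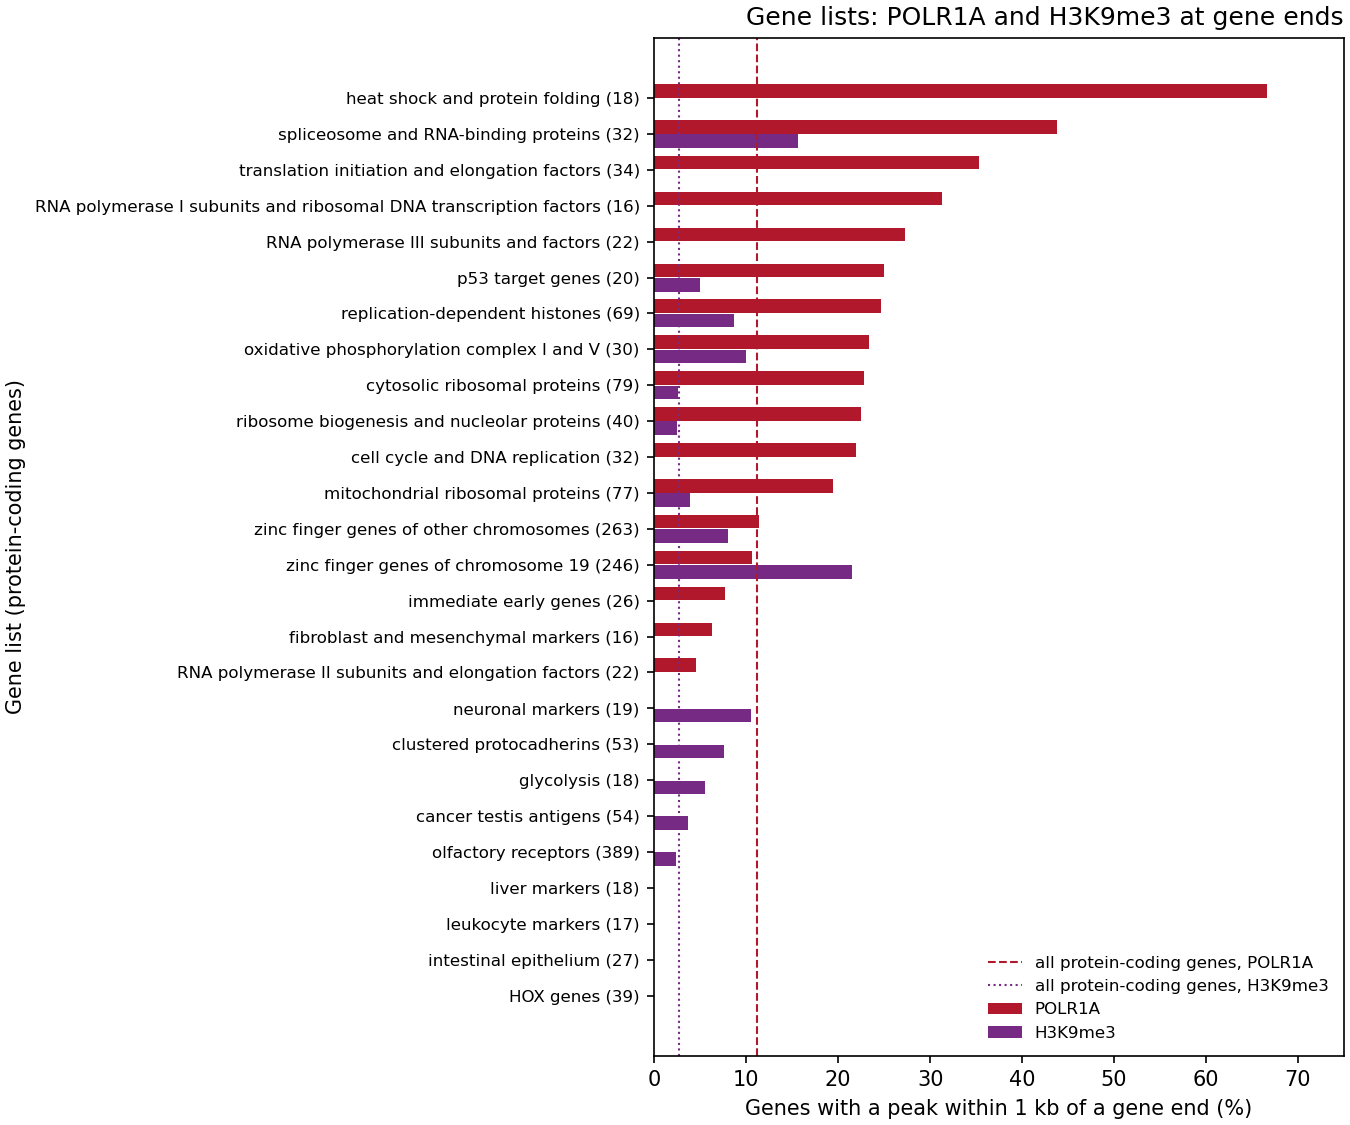
Share of the protein-coding genes of each list (y axis, number of genes in brackets) with a POLR1A or H3K9me3 peak within 1 kb of a gene end (x axis, %), with vertical lines at the shares of all protein-coding genes, 11.2% and 2.70%. Heat shock genes reach 66.7% for POLR1A and zinc finger genes of chromosome 19 reach 21.5% for H3K9me3.

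The last comparison concerned the known template of RNA polymerase I. The annotation placed 3 45S ribosomal RNA units on chromosome 21, RNA45SN2 (8205988 to 8219302), RNA45SN3 (8389035 to 8402343) and RNA45SN1 (8433222 to 8446572), and none of the 4 lists had a peak inside any of these 3. At the mean density of the 4 lists 0.789 peaks would fall there, so a count of 0 does not differ from that density. The mean density need not hold for POLR1A at its known template, so the count does not show whether peaks are missing there. POLR1A peaks lay in the sequence between the units. One spanned 8219750 to 8220204, past the higher end of RNA45SN2, with a POLR1A fold enrichment of 11.01, and it overlapped an H3K9me3 peak of 12.9. Others spanned 8228496 to 8228917 (13.5, with POLR2A at 7.80 and H3K9me3 at 5.32) and 8234103 to 8234787 (11.9, with H3K9me3 at 7.31). The annotation also gives scaffold positions for RNA45SN4 (122273 to 135645) and RNA45SN5 (105424 to 118780), which could not be joined to the contigs of the lists by name, so these units were not analysed here. An unlocalised contig of chromosome 22 had POLR2A peaks of 6.23 (124728 to 124873) and 23.04 (135068 to 135274). Those positions would lie in RNA45SN4 if it is the same scaffold. The contig also had 5 POLR1A peaks at higher positions, from 139289 on. The strongest of them, 11.06, spanned 168738 to 169035 and overlapped a POLR2A peak of 16.85 (168676 to 169024). Another 5 POLR1A peaks, up to 15.3, were on an unplaced contig, none of them between 105424 and 118780. Both contigs were chosen after the data were examined. Whether they hold 45S sequence beyond the annotated units was not examined, so their POLR1A peaks may or may not lie outside it. No list had a peak on any of the 17 genes for 5S ribosomal RNA, a product of RNA polymerase III. Near RNA5S17, within 1 kb, lay a POLR1A peak of 5.19.

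**Figure D4:**
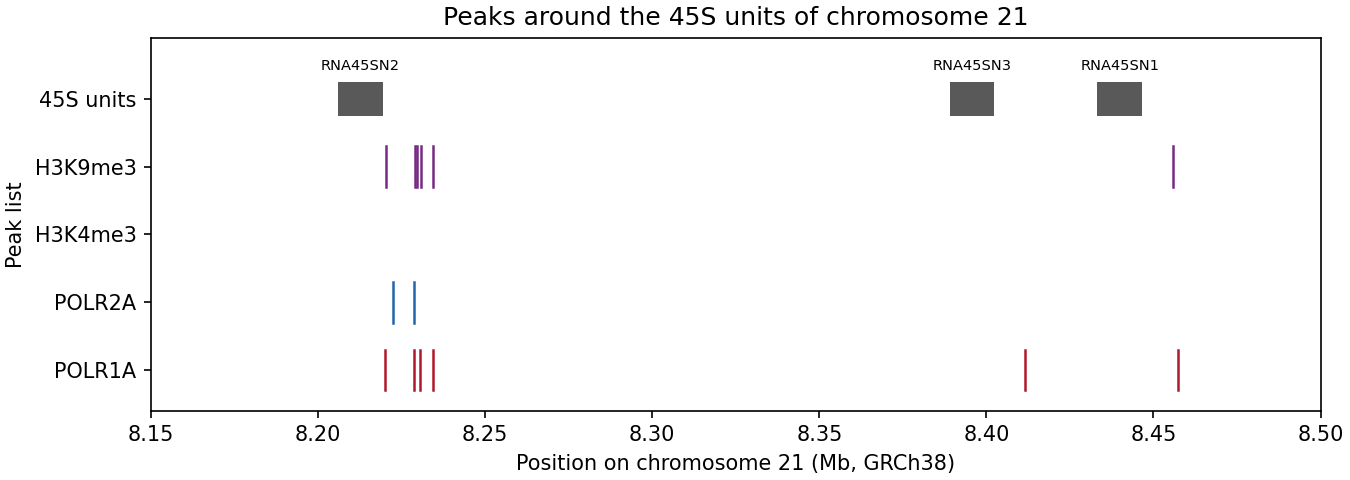
Midpoints of the peaks of each list (coloured marks, not drawn to peak width) and the 3 45S units (grey, to scale) along chromosome 21 (x axis, Mb, GRCh38). No mark falls inside a unit, and the POLR1A mark nearest to RNA45SN2 starts at 8219750.

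Among other non-coding genes, given as shares without a test, POLR1A was at the ends of 5 of 20 small RNA polymerase III genes (RN7SL2 6.38, RN7SL1 6.04, RN7SK 6), 11 of 42 small nuclear RNA genes (RNVU1-30 7.90) and 7 of 30 snoRNA host genes (SNHG29 10.2, SNHG10 9.17, GAS5 8.37). Transfer RNA genes had POLR1A in 41 of 429 cases (9.56%) and POLR2A in 158.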

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

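The tests of sites shared by all lists, of the transposase background, of H3K4me3 strength and of the 5S array were chosen after the result was seen. The margins were chosen after the data were examined, and what their test and that of list length should show was written before those tests were run.

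POLR1A peaks overlapped H3K9me3 more often than POLR2A peaks, by 12.08 percentage points. Repeat-rich chromosome ends and gene-free margins could not account for all of it, since 8.72 points (interval 7.08 to 10.7) were left without them. The longer POLR2A list could not either: against the 3812 POLR2A peaks of highest −log10 q the difference was 8.39 points (6.23 to 10.9). With the margins left out and all 4 lists cut to equal length, which also shortens the H3K9me3 list, 4.73 points were left. Without sites shared by all 4 lists 7.21 points (4.81 to 10.0) were left. Such sites carry H3K9me3 by definition, so the fall says nothing about how much they account for, and only the remainder shows that they are not all of it. Antibody background at repeats outside these margins may contribute and was not tested, and a difference between the polymerases themselves stays open as well.

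POLR1A peaks lay at the strongest POLR2A peaks. Among H3K4me3 peaks of like fold enrichment and width the odds ratio of POLR1A for POLR2A was 14.5 (interval 10.4 to 20.6). It ranged from 7.05 to 80.7 over 3 alternatives. H3K4me3 strength alone is therefore unlikely to account for the presence of both polymerases at the same peaks. POLR2A was taken as present or absent there, so the rise with POLR2A strength was not tested. Background cutting of the transposase at open promoters stays open: outside the margins the H3K9me3 list, whose mark is not one of active promoters, also met the strongest of 10 equal groups of POLR2A peaks 3.39 times as often as the weakest 8 (8.09% against 2.39%, interval 2.60 to 4.26). The ratio for POLR1A was 9.28 (55.9% against 6.02%). Background can differ between antibodies, so the H3K9me3 ratio does not give the size of the background in the POLR1A list. Control antibody samples, which would measure it, were not used here.

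No list had a peak inside the 45S units of chromosome 21. Loss of multi-copy sequence at mapping may be the cause, but the tables cannot decide it: the 16 genes RNA5S1 to RNA5S16 of the 5S array also held 0 peaks of the 4 lists, where the mean peak density gives only 0.204. A true absence and a mapping loss cannot be told apart here. POLR2A peaks of 6.23 and 23.04 on an unlocalised contig of chromosome 22 lie at positions that fit those of RNA45SN4, and if that unit is on this contig, not all 45S sequence was lost. The unit could not be joined to the contig by name, so this stays open too.

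The H3K4me3 overlap of POLR1A peaks exceeded that of POLR2A peaks by 15.78 points, but by 2.67 at a −log10 q of at least 5 (permutation p = 0.649), and with lists of equal length it was lower by 13.8 points. Peaks in sequence outside the comparisons stood out by count, each above the limit of 3. On unplaced, random, alternate and patch contigs lay 261 POLR1A, 286 POLR2A, 259 H3K4me3 and 645 H3K9me3 peaks. Chromosome Y held 40 POLR1A, 18 POLR2A and 143 H3K9me3 peaks. The mitochondrial genome held 9 POLR1A, 15 POLR2A, 5 H3K4me3 and 7 H3K9me3 peaks.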

How the results depend on the processing

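Settings that left out chromosome margins or sites shared by all lists, and the test without olfactory receptors, were chosen after seeing the data. Of 72 alternatives to the overlap shares, 70 kept their direction and stayed past the threshold. The exceptions were H3K4me3 with H3K9me3 (0.898%) and H3K9me3 with H3K4me3 (0.940%) without sites shared by all 4 lists. All sites removed there are overlaps of both marks, so the shares had to fall and this setting decides nothing for them. The H3K9me3 difference between the polymerases stayed positive in all 10 alternatives, from 4.73 to 16.7 points. The H3K4me3 difference was 2.67 points at a −log10 q of at least 5 and reversed to -13.8 points with lists of equal length, which cut the POLR2A and H3K4me3 lists to their strongest peaks. Among H3K4me3 peaks of like fold enrichment and width, the odds ratio of POLR1A for POLR2A (14.5) was 80.7 at a −log10 q of at least 5, 7.05 with equal lengths and 14.48 without margins; these 3 settings were chosen after seeing the data. So were those for the odds ratio of POLR1A with H3K9me3 at gene ends (7.23), which was 5.51 within classes of fold enrichment, 6.31 at a −log10 q of at least 5, 4.97 with equal lengths and 7.39 without margins. Gene-end shares of summits moved with the window by construction: with 500 bp they were 40.8% for POLR1A, 32.1% for POLR2A, 41.96% for H3K4me3 and 1.63% for H3K9me3, and with 2 kb 49.2%, 41.6%, 67.7% and 3.83%. At a −log10 q of at least 5 they were 55.4%, 57.8%, 64.1% and 2.14%, and with equal lengths 70.9% for POLR2A, 84.7% for H3K4me3 and 2.07% for H3K9me3. Without margins POLR1A had 48.2%. At a −log10 q of at least 5, 1052 genes had both polymerases (2114 in the main analysis) and of the 9 lists called for POLR1A only heat shock, spliceosome and olfactory receptor genes were still called, while cell cycle genes were called in addition (18.75% against 5.34%). Without the olfactory receptors 7 were called. Among alternatives to single gene list calls, 26 lost the call. Calls that held are not counted, because some could not change: equal lengths leave the POLR1A list uncut, and the windows at gene ends do not enter the gene bodies. Another 4 alternatives changed direction without a call: histone genes for POLR1A among genes with POLR2A (13.8% at a −log10 q of at least 5 and 42.1% with equal lengths) and for H3K9me3 at the ends (0% in both). No paired analysis was possible because each target has 1 peak list with no values per replicate. For the same reason no replicate could be left out. Read depth is unknown, so a missing peak is no evidence of absence.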

Other observations

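The strongest POLR1A peaks lay mostly near chromosome ends and gene-free intervals. Of the 40 POLR1A peaks of highest fold enrichment, 30 lay within the margins of chromosome ends and gene-free intervals, against 23 of 40 for POLR2A, 15 of 40 for H3K9me3 and 3 of 40 for H3K4me3. In all, 8.53% of POLR1A peaks and 2.62% of POLR2A peaks lay there. Of the 325 POLR1A peaks in these margins 56.0% overlapped H3K9me3 and 48.3% POLR2A, and of the 3487 outside 11.8% and 73.9%. The highest POLR1A value, 42.4, was on chromosome 10 from 133787106 to 133787506, at the last position covered there, and overlapped POLR2A and H3K9me3. The third, 40.0, was at the end of chromosome 22, from 50807876 to 50808489, and overlapped all 3 other lists. The strongest outside the margins was on chromosome 20 from 45313250 to 45313496, with 37.0, and overlapped POLR2A but neither mark. These sites were chosen after their values were seen.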
